A study of Caenorhabditis elegans with 24 samples.

How the data were processed

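Embryos of the C. elegans strain N2 were taken from cut adults by mouth pipette and staged at 8 times from 60 to 500 min after the 4-cell stage, per the labels. Each sample held 50 embryos, and each stage had 3 samples. In the labels, replicates 1 and 2 of a stage share a running sample number. Total RNA was extracted with TRIzol and eluted in 1.5 µl of water, of which 0.5 µl went into CEL-Seq. CEL-Seq reads only the 3′ end of a transcript, so isoforms that share an end were not told apart.

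The deposited values were raw counts per gene, which the authors made with HTSeq, per the submitters' processing notes. The aligner, the genome build, the annotation and the strand of counting are not given in the sources used here. Genes that overlap another gene on either strand were therefore marked as uncertain. The deposited counts had no normalization. They were whole numbers and shared 1 highest value, 1023, in all 24 libraries. A 5-base molecular identifier has 1024 possible forms, so counting distinct identifiers would give a limit close to 1023, though not exactly that value. The labels do not state such counting. Large values are compressed under such a limit, and 644 genes exceeded 500 counts in some library.

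The table held 20779 entries, of which 92 were ERCC spike-ins (RNA standards) and 20687 were worm genes. By identifier, 20080 worm genes matched the WBcel235 annotation, and the unmatched 607 held 0.424% of the counts. Coordinates came from that annotation and symbols were matched by identifier, never by position. All 24 data columns were used, so 0 were left unused. The spike-ins made up 2.36 to 10.21% of the counts of a library and were left out of library sizes and of every test. Worm totals per library ranged from 172620 to 977908. A floor of 3 counts, the upper limit that a count of 0 allows, stood for 3.07 to 17.38 CPM. Intervals and floors cover counting error only.

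Genes were tested with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr (minimum count 10, minimum total 15) kept 8279 genes, which held 98.21% of the counts. Library sizes were scaled by TMM factors, which ran from 0.78 to 1.171, and CPM per stage use them. A quasi-likelihood model with stage as a factor was fitted robustly to all 24 libraries, which leaves 16 residual degrees of freedom. The biological coefficient of variation was 0.192. The time course test covered all stages, and 8 contrasts compared 500 with 60 min and each stage with the one before it. The p-values were adjusted by Benjamini and Hochberg within each contrast, and a gene passed at an adjusted p below 0.05. These p-values measure only the spread between samples. Tests were two-sided.

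Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. A list needed 5 tested genes, and p-values were adjusted over the 256 tests of 32 lists and 8 contrasts. Of these tests 80 passed with the preset correlation. With the estimated correlation 5 passed, all of them among the 80, namely the cuticle list from 180 to 225 min, the vacuolar ATPase family from 330 to 410 and from 410 to 500 min, and the flp and hedgehog-related families from 410 to 500 min. Some genes stood in 2 lists, such as lin-28 and nhl-2 in both miRNA lists. The contrasts, tests, lists, named-gene rule and first set of alternatives were chosen before the data were examined.

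Genes were named by a rule. A named gene passed its contrast, had no overlap in CPM between the 3 libraries of each stage and had a mean of at least 50 CPM in the higher stage. The 10 highest and 10 lowest changes were named for 500 against 60 min and the 3 highest and 3 lowest for each step. For each list and contrast described, up to 3 called members in the majority direction and 1 in the other were named. Any member of the miRNA, Hox and early zygotic lists was open to naming. The time course names were taken from the 10 genes of lowest p. A few genes that the rule names are not reported here. Non-overlap of 3 against 3 libraries arises in 10% of splits by chance. Folds against stages with 0 counts were computed against the floor summed over the stage. For the genes named as highest or lowest changes, stages with 1 to 3 counts got an exact counting interval. List members with so few counts have a fitted log2 change without such an interval.

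The first set of alternatives was DESeq2 size factors within edgeR, library size alone, no filter, a filter of over 10 CPM in at least 3 libraries, DESeq2 1.42.0, a replicate block, a fit to the 6 libraries of each contrast, and leaving out each library and each replicate series. The 10 CPM filter was meant to be stricter but kept 10004 genes for the test of genes changing over the 8 stages, more than the 8279. Further alternatives were chosen after seeing the data. These were a correction for identifier collisions, genes over 500 counts left out, scaling to the spike-ins with no value over 500, and the 4 libraries with most vitellogenin left out. Those 4 libraries were 60 and 120 min replicate 1 and 270 and 330 min replicate 2. A pseudocount alternative was not run, since the values were counts.

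Some scalings moved the median log2 change of all genes by more than 0.1, and changes are relative to that. Library size alone moved it by −0.422 for 500 against 60 min, −0.301 for 410 against 330 min, −0.148 for 500 against 410 min and 0.103 for 180 against 120 min. DESeq2 size factors moved it by −0.119 for 120 against 60 min and 0.128 for 410 against 330 min. Spike-in scaling moved it by 0.168 for 180 against 120 min, 0.264 for 330 against 270 min and −0.44 for 410 against 330 min. The collision correction moved it by −0.148 for 500 against 60 min.

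The procedure was tested on simulated data of 5885 genes, of which 58, 53 and 49 carried changes of 1.5-fold, 2-fold and 4-fold. It recovered 100% of 4-fold, 39.6% of 2-fold and 6.9% of 1.5-fold changes, and 2.6% of its calls were false. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The miRNA libraries of the same study were not used here.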

Results

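The series followed messenger RNA through embryogenesis of Caenorhabditis elegans, the companion of a study of how microRNAs regulate genes during animal development. Embryos of the wild-type strain N2 were collected at 8 stages between 60 and 500 min after the 4-cell stage, with 3 replicate libraries per stage and 50 embryos per library. Messenger RNA was measured by CEL-Seq, a method that tags and sequences the 3′ end of polyadenylated transcripts. Worm counts per library ranged from 172620 (120 min, replicate 1) to 977908 (330 min, replicate 3), with a median of 423142, and 8069 to 13281 genes had at least 1 count. One count corresponded to 1.02 to 5.79 CPM (counts scaled to 1 common library total), depending on the library. No value exceeded 1023, which 6 worm genes reached, and 644 genes exceeded 500 counts in at least 1 library.

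Libraries mostly grouped by stage. Same-stage libraries had Spearman correlations of 0.922 to 0.976 across genes, against 0.768 to 0.975 between libraries of adjacent stages and 0.057 to 0.092 between 60 and 500 min libraries. The first principal component held 60% of the variance and the second 17.7%. On the first, 270 min replicate 3 stood at 14.6, between the other 270 min libraries (−5.48 and −5.19) and 330 min replicate 3 (29.41). Measured levels differed within stages in 2 respects that the stages do not name. A term for the replicate 1 libraries called 644 genes higher and 924 lower (edgeR, 8279 genes), whereas the same term for replicate 2 or for replicate 3 called 0, with 865 and 423 genes at an unadjusted p under 0.05. The latter terms were fitted with the replicate 1 deviation left in the spread, so their 0 calls cannot show that only replicate 1 deviated. The summed vitellogenin genes vit-1 to vit-6, which encode yolk proteins made in the adult intestine, ranged from 0 CPM (225 min and 330 min, replicate 1) to 1305 CPM (60 min, replicate 1). The next highest sums were 1095 CPM at 330 min replicate 2, 909.5 CPM at 120 min replicate 1 and 759 CPM at 270 min replicate 2.

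**Figure D1:**
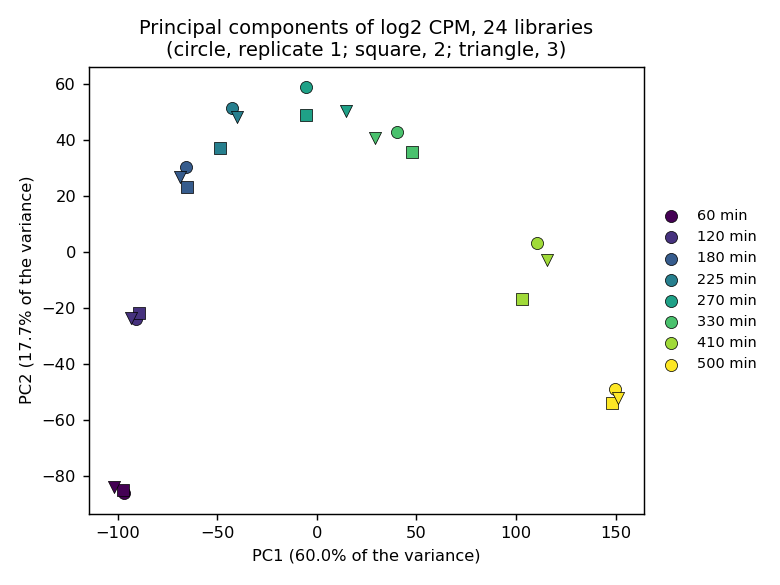
Principal components 1 (60% of the variance, x axis) and 2 (17.7%, y axis) of log2 CPM of the tested genes, 1 point per library, coloured by stage and shaped by replicate (circle 1, square 2, triangle 3). The 24 libraries lie in order of stage along an arc from 60 to 500 min.

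Nearly all tested genes changed with developmental time. Among the 10 genes with the lowest p were W06F12.2, dod-6, F31D4.5, T19B10.5, abu-13, mct-3, dsl-2, lpr-5 and clc-8. The gene dsl-2, which encodes a ligand of the DSL family that binds Notch receptors, was highest at 120 min at 1098 CPM and stood at 1.77 CPM at 270 min. The gene lpr-5, which encodes a lipocalin-related protein of the apical matrix, went from 0.668 CPM at 60 min to 983 CPM at 410 min, and the claudin-like clc-8 reached 864 CPM at the same stage. The gene mct-3 went from 0.573 CPM at 330 min to 824.5 CPM at 500 min. The gene abu-13, a member of a family with repeated sequence, is given as uncertain. By edgeR's quasi-likelihood F test over the 8 stages, 7585 of 8279 tested genes (91.6%) passed a Benjamini-Hochberg threshold of 0.05 and 694 did not. Of the 7585, 1798 had their highest mean at 60 min, 950 at 120 min, 600 at 180 min, 379 at 225 min, 312 at 270 min, 367 at 330 min, 805 at 410 min and 2374 at 500 min. F31D4.5 and abu-13 overlap another gene, and their values are uncertain.

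**Figure D2:**
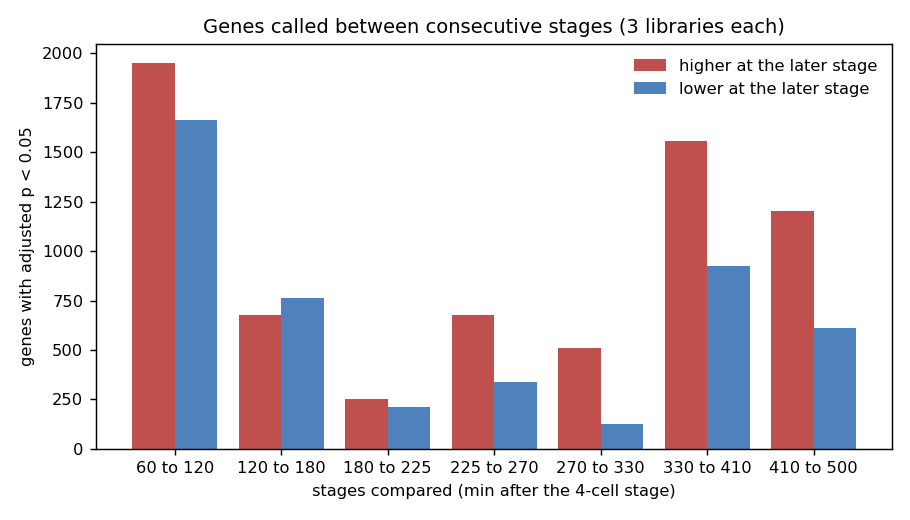
Genes higher (red bars) and lower (blue bars) at the later stage of each consecutive step, 3 libraries per stage. The y axis gives the number of genes with an adjusted p below 0.05 and the x axis the stages compared, in minutes after the 4-cell stage. The step from 60 to 120 min had 1950 genes higher and 1662 lower and the step from 180 to 225 min 254 higher and 213 lower.

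From 60 to 500 min, the 10 largest rises and the 10 largest falls by fitted log2 change, which for genes with 0 counts depends on the prior count added, were of genes with 0 counts at 60 or at 500 min. The gene ptr-4, which encodes a patched-related membrane protein of the apical epidermis (chromosome X, 6060758 to 6065986, WBcel235), had 0 counts at 60 min and 942 ± 142 CPM at 500 min (SD, n = 3), at least 440-fold higher against a floor of 3 counts summed over the 3 libraries of the stage. Also at 0 counts at 60 min were K08B12.1 (914 ± 125 CPM, at least 465-fold higher), the small heat shock protein gene hsp-12.1 (689 ± 111.9 CPM, at least 320-fold), rml-3 (641 ± 151 CPM), T04C12.1 (557 ± 48.2 CPM) and ric-3, a chaperone of acetylcholine receptors (519 ± 97.4 CPM). The gap junction gene inx-6 (chromosome IV, 12746584 to 12749721) reached 494.5 ± 95.7 CPM, at least 264-fold higher, and unc-53, which guides migrating cells and axons, hhat-1 and tbc-7 reached 477, 471 and 461 CPM. In the other direction pes-10, transcribed in early somatic blastomeres (chromosome II, 12846191 to 12847836), went from 644 ± 102 CPM at 60 min to 0 counts at 500 min, at least 259-fold lower. The forkhead gene fkh-3 (chromosome X, 13421822 to 13423440) went from 399 ± 81.7 CPM to 0 counts (at least 173-fold lower), as did Y43F11A.1 (563 ± 46.2 CPM), EEED8.12 (525.5 ± 33.7 CPM), sgnh-1 (471 ± 29.9 CPM), Y106G6D.2 (422 ± 44.9 CPM), ZK899.6 (417 ± 28.4 CPM) and EEED8.4 (394 ± 30.2 CPM). The Skp1-related genes skr-8 (802 ± 95.1 CPM at 60 min, 0 counts at 500 min) and skr-9 (773.5 ± 127 CPM, 0 counts) are near-identical copies, and their separate values are uncertain. Adjusted p of these 20 genes ranged from 2.32e-18 (rml-3) to 6.27e-10 (pes-10). In all, 3814 genes were higher and 2751 lower at 500 min (edgeR, 8279 tested), 3512 and 2458 of them by at least 2-fold. The genes ptr-4, K08B12.1, skr-8 and skr-9 exceeded 500 counts in a library. Without the replicate 1 libraries 6544 genes passed, 6333 of them among the 6565. K08B12.1, unc-53 and hhat-1 overlap another gene, and their values are uncertain.

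Oocyte, germline and cell cycle transcripts were lower at 500 min than at 60 min. Of 28 tested maternal and oocyte genes, 22 were lower and 4 higher (camera adjusted p = 0.00619 with the preset correlation, adjusted p = 0.493 with an estimated correlation). The gene oma-1, which encodes a zinc finger protein of the oocyte-to-embryo transition, fell from 796 ± 80.5 to 11.8 ± 7.24 CPM (log2 −5.80, SE 0.705), nos-2, a nanos homologue, from 444 ± 66.0 to 5.87 ± 1.19 CPM (log2 −6.24), and mex-6 from 219 ± 23.7 to 4.33 ± 1.89 CPM (log2 −5.68). The polarity kinase gene par-1 rose from 115 ± 23.4 to 845 ± 111 CPM (log2 2.86). Germline and P granule genes fell in 17 of 19 and rose in 0 (camera adjusted p = 0.000149; adjusted p = 0.216 with an estimated correlation), among them gcna-1 (291 ± 9.22 to 4.62 ± 4.64 CPM), the meiotic axis gene htp-3 (79.7 ± 16.6 to 1.02 ± 1.77 CPM) and meg-2 (43.8 ± 6.21 to 0.51 ± 0.884 CPM). Cell division and DNA replication genes fell in 39 of 41 (camera adjusted p = 5.63e-19; adjusted p = 0.0811 with an estimated correlation). The replicative helicase genes mcm-2 and mcm-5 went from 482 ± 45.1 to 8.38 ± 8.61 CPM (log2 −6.34) and from 474 ± 45.6 to 4.87 ± 4.23 CPM (log2 −6.16), and fzy-1, the CDC20 homologue, from 360 ± 60.6 to 6.35 ± 5.15 CPM (log2 −6.13). The kinesin gene klp-7 rose (log2 2.57). Of 25 early zygotic regulators 15 fell and 6 rose (camera adjusted p = 0.00343; adjusted p = 0.219 with an estimated correlation), with a median log2 change of −4.68, or −4.37 with 7 genes of 0 counts set at their bound. Adjusted over the list alone, the counts of these 4 lists were the same. The genes nos-2, par-1, gcna-1, mcm-2 and fzy-1 overlap another gene, and their values are uncertain.

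Genes of differentiated tissues rose over the same interval. Of 34 body wall muscle genes 33 rose and 0 fell (camera adjusted p = 9.14e-07; adjusted p = 0.323 with an estimated correlation). The troponin genes tni-1 (3.37 ± 0.558 to 1229 ± 80.5 CPM, log2 8.41) and tnt-3 (1.34 ± 2.32 to 532 ± 110 CPM, log2 8.39) and the myosin heavy chain gene myo-3 (3.78 ± 4.91 to 862 ± 322 CPM, log2 8.20) changed most, and 17 of the 34 exceeded 500 counts in some library. Of 27 genes of the cuticle and apical matrix 25 rose and 1 fell (camera adjusted p = 6.03e-07; adjusted p = 0.0929 with an estimated correlation). Among these, the cuticlin gene cut-6 went from 0 counts to 327 ± 6.27 CPM (at least 163-fold higher), the collagen gene lon-3 from 0 counts to 132 ± 16.8 CPM (at least 64-fold) and dpy-2 from 0.668 ± 1.16 to 462 ± 109 CPM. The fibrillin-related fbn-1 was lower at 500 min (log2 −1.35) after its highest mean of 1076 CPM at 270 min. In the list of epidermal specification and junction genes 24 of 29 rose and 3 fell (camera adjusted p = 0.000248; adjusted p = 0.323 with an estimated correlation), including the intermediate filament gene ifa-3 (0 counts to 267 ± 74.1 CPM, at least 120-fold), the attachment gene let-805 (log2 8.09) and the cell fusion gene eff-1 (log2 6.73). In the same list die-1 fell (log2 −2.23). Intestinal genes rose in 13 of 17 and fell in 1 (camera adjusted p = 0.00423; adjusted p = 0.31 with an estimated correlation), with 2 lower when adjusted over the list alone. The genes ifd-2 (at least 65.6-fold), inx-16 (0.498 ± 0.863 to 392 ± 35.4 CPM) and the sodium-proton exchanger gene nhx-2 (at least 55.2-fold) led that list. Its lower member acp-6 fell (log2 −1.79). Pharyngeal genes rose in 14 of 15 (camera adjusted p = 0.000719; adjusted p = 0.291 with an estimated correlation), among them phat-5 (0 counts to 205 ± 138 CPM), pqn-32 (1.34 ± 2.32 to 480.0 ± 309 CPM) and the homeobox gene ceh-34 (0.668 ± 1.16 to 246 ± 47.3 CPM). Apart from the intestine, counts adjusted over the list alone were the same. The genes lon-3, fbn-1, eff-1, pqn-32 and ceh-34 overlap another gene, and their values are uncertain.

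Most genes of the neuronal lists rose as well, although the list tests of fate regulators and Hox genes did not pass. Of 24 pan-neuronal genes 21 rose and 0 fell (camera adjusted p = 0.000463; adjusted p = 0.334 with an estimated correlation): ida-1 went from 0 counts to 153 ± 80.01 CPM (at least 90.2-fold), the synaptotagmin gene snt-1 from 0 counts to 76.9 ± 19.1 CPM (at least 41.7-fold) and rab-3, a synaptic vesicle GTPase, from 0.668 ± 1.16 to 252 ± 98.1 CPM. Cilia genes rose in 34 of 36 and fell in 1 (35 and 1 adjusted over the list alone; camera adjusted p = 0.000399; adjusted p = 0.442 with an estimated correlation), with a median log2 change of 5.77, or 4.90 with 14 genes of 0 counts set at their bound. The genes mks-2 (0 counts to 68.0 ± 21.4 CPM), che-11 (62.7 ± 33.3 CPM) and tmem-231 (67.7 ± 15.8 CPM) were among them, and the centriolar gene hyls-1 fell (log2 −1.17). Of 24 neuronal fate regulators 17 rose and 4 fell, and the list test did not pass (camera adjusted p = 0.0542). The gene unc-42 went from 0 counts to 189 ± 53.7 CPM (at least 103-fold), egl-13 from 1.04 ± 1.80 to 528 ± 32.2 CPM and ast-1 from 0 counts to 120 ± 23.03 CPM (at least 56-fold). The proneural gene ngn-1 fell (log2 −4.16). In the neurotransmitter list 4 genes had counts enough for a test, so it had no list test. In it snf-11, a GABA transporter, rose from 2.74 ± 3.18 to 316.5 ± 70.6 CPM and ace-1, an acetylcholinesterase, from 0.997 ± 1.73 to 199 ± 72.6 CPM. The gene cat-4 rose from 0.668 ± 1.16 to 53.4 ± 20.1 CPM. The remaining tested gene, tdc-1, had its highest mean at 60 min. All 5 tested Hox genes rose between 60 and 500 min (camera adjusted p = 0.142), by log2 6.41 for php-3, 4.62 for mab-5, 2.86 for nob-1, 2.64 for lin-39 and 1.10 for ceh-13. Counts adjusted over the list alone were the same for the pan-neuronal, fate and Hox lists. The genes rab-3, che-11, ast-1 and cat-4 overlap another gene, and their values are uncertain.

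**Figure D3:**
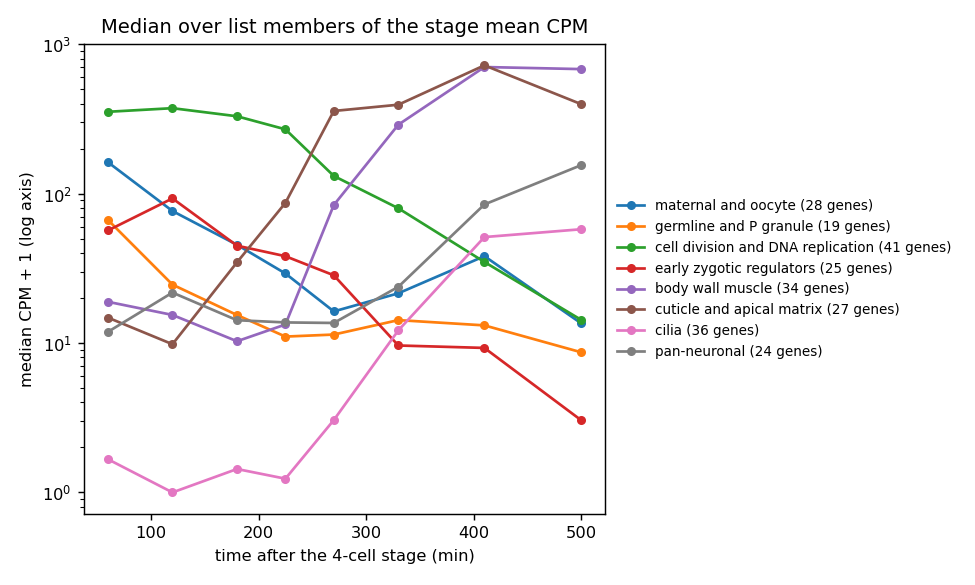
Median over list members of the stage mean CPM, drawn plus 1 on a log y axis, against minutes after the 4-cell stage (x axis). Each line is 1 of 8 gene lists written before the data were examined, with the number of tested genes in the key. The median of cell division genes went from 352 CPM at 60 min to 13.3 CPM at 500 min and that of body wall muscle genes from 17.9 to 680 CPM.

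The series concerns microRNAs, and the genes listed beforehand for the miRNA pathway did not move together. Of 17 tested genes of the miRNA pathway, 6 were higher and 7 lower at 500 min than at 60 min, also when adjusted over the list alone, and the list test did not pass (camera adjusted p = 0.489, median log2 change −0.42). The Argonaute gene alg-1 (chromosome X, 13949110 to 13956261) rose from 90.2 ± 17.5 to 409 ± 51.02 CPM (log2 2.14, SE 0.216, adjusted p = 5.05e-11). Its paralogue alg-2 (chromosome II, 873212 to 879885) went from 219 ± 7.14 CPM at 60 min to 490.1 ± 43.7 CPM at 120 min and to 115 ± 11.9 CPM at 500 min (log2 −0.89 against 60 min, SE 0.211, adjusted p = 0.000266). Both subunits of Microprocessor, which cleaves primary miRNA transcripts, fell: pash-1 (chromosome I, 10598673 to 10606621) from 249 ± 20.5 CPM at 60 min to 39.1 ± 14.7 CPM at 120 min (log2 −2.58, adjusted p = 2.06e-08) and 26.02 ± 3.84 CPM at 500 min. The other subunit, drsh-1, went from 53.5 ± 10.6 to 7.38 ± 4.92 CPM (log2 −3.03). The gene dcr-1, which encodes Dicer, fell from 128 ± 11.3 to 42.5 ± 16.12 CPM (log2 −1.73) and the dsRNA-binding gene rde-4 from 201 ± 31.1 to 18.9 ± 5.22 CPM (log2 −3.49). The GW182 gene ain-1 rose from 178 ± 71.8 CPM to its highest mean of 1203 ± 141 CPM at 225 min and stood at 606 ± 199 CPM at 500 min (log2 1.77). The other GW182 gene, ain-2, had 47.4 ± 15.5 and 33.2 ± 3.24 CPM (adjusted p = 0.373). The poly(A)-binding genes pab-1 (log2 0.67) and pab-2 (log2 1.83), nhl-2 (log2 1.36) and lin-28 (178 ± 58.0 to 372 ± 36.3 CPM, log2 1.02) were higher, and the deadenylase gene ccr-4 (log2 −0.60) and the exonuclease gene xrn-2 (log2 −0.59) lower. The genes ccf-1 (adjusted p = 0.283), xrn-1 (adjusted p = 0.354) and hsp-90 (adjusted p = 0.0592) did not pass. Under scaling to the spike-ins, 4 members were higher and 4 lower, with a median log2 change of −0.33. The genes alg-2 (edgeR adjusted p = 0.2), lin-28, pab-1, ccr-4 and xrn-2 no longer passed. Their log2 changes were then −0.83, 0.92, 0.76, −0.54 and −0.58, close to those with the reported scaling. Of these, pab-1 also did not pass with library size alone (log2 0.24, edgeR adjusted p = 0.266). Neither did it without replicate 1 (log2 0.575, adjusted p = 0.0559) or without replicate 3 (log2 0.514, adjusted p = 0.0731). The gene xrn-2 did not pass without replicate 2 (log2 −0.666, adjusted p = 0.08) or replicate 3 (log2 −0.546, adjusted p = 0.131). The gene ccf-1 was lower with library size alone and without replicate 1, and hsp-90 higher by DESeq2 and with the replicate block. Of the 17 genes, 5 exceeded 500 counts in a library. The miRNAs themselves were not analysed here. The genes drsh-1, lin-28, xrn-1 and hsp-90 overlap another gene, and their values are uncertain.

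**Figure D4:**
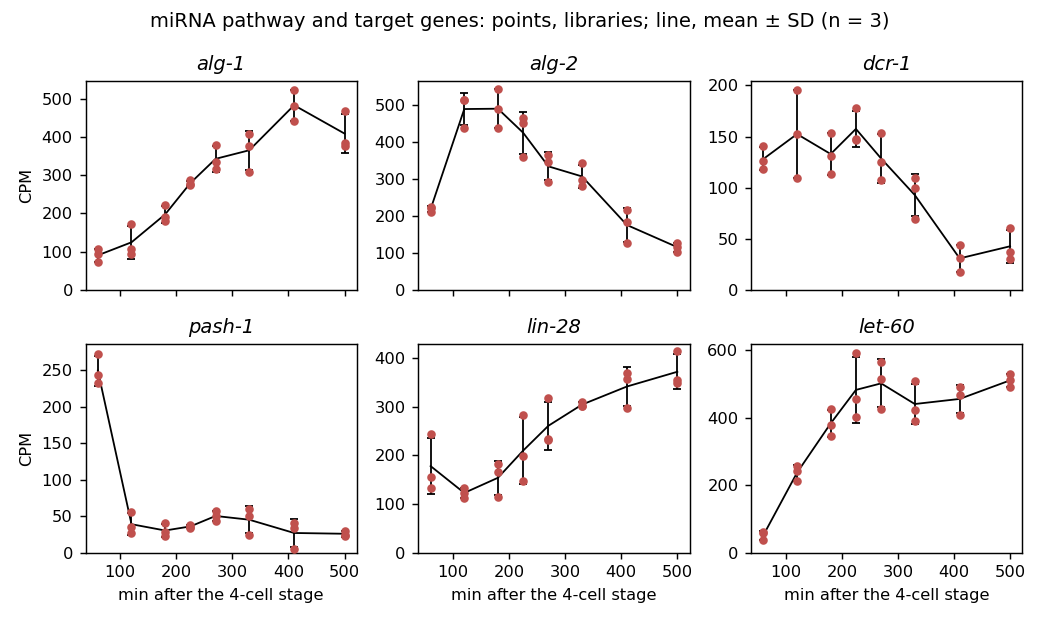
CPM (y axis) of alg-1, alg-2, dcr-1, pash-1, lin-28 and let-60 against minutes after the 4-cell stage (x axis), 1 panel per gene. Points are single libraries, and lines with bars are the mean ± SD (n = 3). The gene alg-1 was at 90.2 CPM at 60 min and 409 CPM at 500 min, and pash-1 at 249 CPM at 60 min and 39.1 CPM at 120 min.

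Of the genetically characterised miRNA targets, all 10 with counts enough for a test were higher at 500 min than at 60 min, also when adjusted over the list alone, although the list as a whole did not pass against other genes (camera adjusted p = 0.0775, median log2 change 3.37). The lsy-6 target cog-1 rose by log2 6.50 to 212 ± 31.2 CPM (SE 0.542), from 2, 0 and 1 counts in the 60 min libraries. The let-7 family target let-60, a Ras gene, rose from 52.3 ± 13.02 to 511 ± 18.7 CPM (log2 3.24, edgeR adjusted p = 6.25e-15). Spike-in scaling left 9 of the 10 higher, without lin-28 (log2 0.92, edgeR adjusted p = 0.16). Leaving out the 4 libraries with most vitellogenin also left 9, without hbl-1 (edgeR adjusted p = 0.0854). The log2 change of hbl-1 was then 3.20, against 3.49 with all libraries. Several were highest before 500 min. The gene cdh-3 had its highest mean of 270 ± 53.3 CPM at 410 min and 37.1 ± 19.6 CPM at 500 min. Likewise egl-1, a trigger of programmed cell death and a target of the mir-35 and bantam families, had 77.2 ± 15.8 CPM at 410 min and 19.3 ± 13.3 CPM at 500 min. The mean of hbl-1 was 85.6 ± 67.9 CPM at 410 min and 9.20 ± 3.09 CPM at 500 min (adjusted p = 0.0438 for 500 against 60 min, but 0.0589 with library size alone, 0.0574 after the collision correction, 0.127 without replicate 2 and 0.0814 without replicate 3). Further rises against 60 min were log2 3.78 for daf-12, 2.47 for vav-1, 1.36 for nhl-2, 1.21 for sup-26 and 1.02 for lin-28. From 410 to 500 min cdh-3, egl-1, hbl-1 and sup-26 fell and daf-12 rose. The genes lin-14, lin-41, unc-29 and mef-2 had too few counts for the test. The genes cog-1, vav-1 and lin-28 overlap another gene, and their values are uncertain.

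Of the consecutive steps, that from 60 to 120 min had the most calls, also under every alternative that covered all steps. More early zygotic regulators rose than fell, and more maternal genes fell than rose. The T-box gene tbx-43 went from 0 counts to 162 ± 12.1 CPM (at least 78.3-fold higher, adjusted p = 4.1e-10), the peroxisomal catalase gene ctl-2 from 0 counts to 78.8 ± 13.9 CPM (at least 37.2-fold) and Y116F11A.1 from 0 counts to 55.4 ± 23.2 CPM. The GATA factor gene end-3, which specifies endoderm (52.2 ± 21.1 CPM to 0 counts, at least 22.1-fold lower), E02H4.6 (70.6 ± 6.09 CPM to 0 counts) and hlh-25 (55.6 ± 13.3 CPM to 0 counts) went the other way. Early zygotic regulators moved both ways: 14 of 25 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.119). The gene elt-1, which encodes a GATA factor of the epidermis, rose from 32.02 ± 15.4 to 694 ± 110 CPM (log2 4.36), the pharynx selector pha-4 from 37.4 ± 11.2 to 643 ± 130 CPM (log2 4.13), ceh-27 from 1.17 ± 1.04 to 212.5 ± 24.99 CPM (log2 7.03) and hnd-1 from 27.5 ± 9.60 to 276 ± 61.96 CPM (log2 3.36). In the other direction pes-10 fell from 644 ± 102 to 130.4 ± 61.1 CPM and ref-1 from 187 ± 28.3 to 62.6 ± 11.1 CPM. The genes tbx-37 and tbx-38, and hlh-25 and hlh-27, are pairs of similar genes whose separate values are uncertain, and all 4 fell. Among the Hox genes php-3 (log2 5.37), nob-1 (3.91 ± 2.37 to 78.3 ± 6.30 CPM) and ceh-13 (94.2 ± 54.3 to 772 ± 46.6 CPM) rose and lin-39 fell (31.3 ± 11.8 to 2.52 ± 2.45 CPM), with the same counts adjusted over the list alone (camera adjusted p = 0.0232; adjusted p = 0.15 with an estimated correlation). Maternal and oocyte genes fell in 17 of 28 and rose in 2 (21 and 2 adjusted over the list alone; camera adjusted p = 0.0122; adjusted p = 0.56 with an estimated correlation), led by mex-1 (465 ± 69.3 to 42.3 ± 12.7 CPM) and mex-6 (219 ± 23.7 to 18.6 ± 11.1 CPM). One of the 2 that rose was par-2 (105 ± 0.778 to 269.6 ± 25.8 CPM). Germline genes fell in 14 of 19 and rose in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.000172; adjusted p = 0.231 with an estimated correlation). Under scaling to the spike-ins, 9 early zygotic regulators rose and 8 fell, 10 maternal genes fell and 8 germline genes fell. The median log2 changes of these lists were then 0.715, −1.26 and −1.62, against 0.795, −1.17 and −1.57 with the reported scaling. Without replicate 3, 8 maternal genes fell. In all, 1950 genes were higher and 1662 lower at 120 min (edgeR), or 602 calls per 10 min of development. The lower genes were more numerous with DESeq2 size factors (1755 higher, 1877 lower), by DESeq2 (1606, 1718), under scaling to the spike-ins (627, 677) and without replicate 1 (1721, 1727). Without replicate 1, 3448 genes passed, 3233 of them among the 3612. The genes ctl-2, end-3, tbx-38, hlh-27 and mex-1 overlap another gene, and their values are uncertain.

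Between 120 and 180 min more early zygotic regulators fell than rose, and more cuticle and apical matrix genes rose than fell. The gene efl-3, which encodes an E2F-like factor, rose from 4.47 ± 1.64 to 591 ± 55.2 CPM (log2 7.01, SE 0.358, adjusted p = 9.57e-17). The bZIP gene zip-7 had 1 count over the 3 libraries at 120 min and 244.5 ± 35.7 CPM at 180 min, a ratio of 292 with a 95% counting interval of 52.1 to 11560, and mnm-2 had 3 counts and 195 ± 64.7 CPM (ratio 77.99, 26.4 to 380.3). C17E4.2 fell from 509 ± 197 to 6.96 ± 5.39 CPM (log2 −5.93), Y43B11AL.1 went from 195 ± 49.7 CPM to 2 counts (ratio 154, 42.2 to 1281) and fbxb-31 from 54.6 ± 17.8 CPM to 1 count (ratio 93.2, 16.19 to 3731). Of 25 early zygotic regulators 11 fell and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.000308; adjusted p = 0.0563 with an estimated correlation). The gene tbx-11 went from 1481 ± 494 to 249 ± 98.96 CPM, the mesodermal gene ceh-51 from 198 ± 31.9 to 11.3 ± 10.1 CPM and pes-1 from 191 ± 38.3 to 43.8 ± 4.18 CPM. The epidermal zinc finger gene lin-26 rose from 138 ± 33.02 to 403 ± 59.4 CPM. Genes of the cuticle and apical matrix rose in 12 of 27 and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 6.28e-06; adjusted p = 0.152 with an estimated correlation). The matrix gene sym-1 went from 16.6 ± 16.04 to 497 ± 77.0 CPM and noah-2 from 6.79 ± 1.10 to 88.6 ± 17.8 CPM. The collagen gene dpy-7 was lower (log2 −3.42). Of the early zygotic regulators, 5 fell under scaling to the spike-ins, with a median log2 change of −0.72 against −0.90 with the reported scaling. In all, 676 genes were higher and 763 lower (edgeR), but 813 and 637 with library size alone. Leaving out 120 min replicate 3 gave 418 genes higher, and without replicate 1, 1335 genes passed, 1163 of them among the 1439. The genes mnm-2, ceh-51, lin-26 and sym-1 overlap another gene, and their values are uncertain.

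The step from 180 to 225 min had 467 calls, the fewest of the steps. The step from 270 to 330 min, with 634, had fewer without replicate 1 (224 against 395), without replicate 2 (12 against 249), without the 4 libraries with most vitellogenin (109 against 467) and in fits to 6 libraries (502 against 521). From 270 to 330 min those 4 libraries take out only replicate 2, so this setting repeats the one without replicate 2. Per 10 min the 2 steps had 103.8 and 105.7 calls. The gene ttx-1, an Otx-type homeobox gene of thermosensory neurons, went from 0 counts to 101 ± 12.8 CPM (at least 53.2-fold higher, adjusted p = 1.7e-10). The cell death specification gene ces-2 went from 1 count to 97.04 ± 31.3 CPM (ratio 156, 95% counting interval 27.6 to 6222) and the insulin-like gene ins-2 from 7.37 ± 4.48 to 266 ± 18.99 CPM (log2 4.95, SE 0.777). The nuclear receptor gene nhr-2 fell from 223 ± 13.9 to 16.8 ± 15.4 CPM (adjusted p = 4.97e-08), Y71A12B.11 from 189 ± 36.9 to 12.9 ± 5.94 CPM (log2 −3.90) and R11A5.3 from 245 ± 71.4 to 18.4 ± 11.8 CPM (log2 −3.75). Cuticle and apical matrix genes rose in 13 of 27 and fell in 0 (18 and 0 adjusted over the list alone), and this list also passed with an estimated correlation (camera adjusted p = 2.12e-16; adjusted p = 0.0277 with an estimated correlation). The gene mlt-8 rose from 2.55 ± 2.52 to 39.5 ± 11.3 CPM, dpy-2 from 1.37 ± 1.396 to 16.6 ± 10.7 CPM and dpy-7 by log2 4.40. Neuronal fate regulators rose in 4 of 24 and fell in 1 (6 and 2 adjusted over the list alone; camera adjusted p = 0.00619; adjusted p = 0.316 with an estimated correlation), among them egl-46 (0 counts to 41.0 ± 10.1 CPM) and ngn-1 (13.6 ± 2.11 to 48.4 ± 22.6 CPM). Of the cuticle and apical matrix genes, 6 rose under scaling to the spike-ins, with a median log2 change of 1.32 against 1.24 with the reported scaling, and 1 neuronal fate regulator rose. Without replicate 3 the cuticle and fate lists had 6 and 1 higher. In all, 254 genes were higher and 213 lower (edgeR). Leaving out 225 min replicate 3 gave 140 and 90, and without replicate 1, 395 genes passed, 341 of them among the 467.

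Body wall muscle, cuticle, epidermal and neuronal fate lists had more genes higher than lower between 225 and 270 min, and cell division genes more lower than higher. The gene unc-3, which encodes a COE factor of cholinergic motor neurons, went from 0 counts to 97.05 ± 30.8 CPM (at least 47.8-fold higher, adjusted p = 4.75e-09), the troponin I gene tni-1 from 1 count to 157 ± 121.8 CPM (ratio 248, 95% counting interval 44.1 to 9831) and the claudin-like clc-6 from 1 count to 149 ± 137 CPM (ratio 241, 42.8 to 9539). The gene zip-7 fell from 356 ± 64.1 to 14.8 ± 9.26 CPM (log2 −4.48), F22B7.9 by log2 3.91 to 4.10 ± 4.78 CPM and skr-14 from 83.5 ± 36.3 to 5.31 ± 5.66 CPM (log2 −3.72). Body wall muscle genes rose in 16 of 34 and fell in 0 (18 and 0 adjusted over the list alone; camera adjusted p = 1.1e-09; adjusted p = 0.192 with an estimated correlation), including the myosin genes unc-54 (1.64 ± 1.76 to 70.3 ± 55.2 CPM) and myo-3 (1.41 ± 2.45 to 60.5 ± 58.3 CPM). Cuticle and apical matrix genes rose in 16 of 27 (18 adjusted over the list alone; camera adjusted p = 1.84e-11; adjusted p = 0.0513 with an estimated correlation), with dpy-7 at 18.6 ± 5.57 and 388 ± 200.4 CPM and mlt-8 at 39.5 ± 11.3 and 509 ± 236 CPM. Epidermal genes rose in 14 of 29 and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 1.98e-08; adjusted p = 0.0929 with an estimated correlation). Neuronal fate regulators rose in 11 of 24 and fell in 1 (13 and 4 adjusted over the list alone; camera adjusted p = 0.000149; adjusted p = 0.153 with an estimated correlation), with unc-42 at 0.943 ± 1.63 and 84.0 ± 33.7 CPM and unc-86 at 4.12 ± 5.16 and 82.9 ± 22.01 CPM. Cell division genes fell in 21 of 41 and rose in 0 (29 and 0 adjusted over the list alone; camera adjusted p = 2.09e-19; adjusted p = 0.0758 with an estimated correlation), led by mcm-6 (172 ± 1.71 to 28.95 ± 4.18 CPM) and mcm-2 (191 ± 38.4 to 43.02 ± 10.2 CPM). Scaled to the spike-ins, 13 body wall muscle, 7 cuticle, 6 epidermal and 5 neuronal fate genes rose, and 2 cell division genes fell. Median log2 changes were then 0.88 for the cuticle, 0.85 for the epidermal and 1.17 for the fate list and −0.73 for cell division, against 0.79, 0.72, 1.08 and −0.83 with the reported scaling. Placed along the mean course of the other series, a test chosen after the data were seen, 270 min replicate 3 lay at 295 min. Without that library 10 body wall muscle genes rose (median log2 change 1.48 against 1.72), as did 11 cuticle, 11 epidermal and 7 fate genes (3 of the last list fell), and 14 cell division genes fell. Median log2 changes of the cuticle, epidermal, fate and cell division lists were then 0.775, 0.671, 0.465 and −0.749. With all libraries they were 0.79, 0.72, 1.08 and −0.83, so that of the fate list moved most of these. Without replicate 2 in both stages 7 muscle genes rose and 9 cell division genes fell. In all, 679 genes were higher and 340 lower (edgeR), and under scaling to the spike-ins 311 were higher and 35 lower. Leaving out 270 min replicate 3 gave 407 higher and 173 lower, leaving out 225 min replicate 2 gave 225 lower, and without replicate 1, 974 genes passed, 838 of them among the 1019. The genes mcm-6 and mcm-2 overlap another gene, and their values are uncertain.

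From 270 to 330 min, more muscle and cilia genes were higher than lower, in a step whose calls depended on single libraries and in which most members of both lists did not pass. Without replicate 2, 0 genes of the muscle and cilia lists rose and 0 cell division genes fell (edgeR, with 10, 7 and 9 at an unadjusted p under 0.05). Their median log2 changes were then 1.18, 0.86 and −0.38, against 1.63, 1.60 and −0.48 with all libraries. Placed along the mean course of the other series, a test chosen after the data were seen, 270 min replicate 3 lay at 295 min, 330 min replicate 3 at 310 min and 330 min replicate 2 at 345 min. The unconventional myosin gene hum-6 rose from 2.08 ± 3.60 to 77.8 ± 31.1 CPM (log2 4.68, SE 0.575, adjusted p = 5.32e-05), F41C3.11 from 6.75 ± 11.7 to 108 ± 38.8 CPM (log2 3.61) and F57B1.6 from 3.63 ± 6.29 to 54.8 ± 29.6 CPM (log2 3.40). The cyclin D gene cyd-1 fell from 585 ± 75.7 to 160.4 ± 76.5 CPM (log2 −1.81, SE 0.258, adjusted p = 6.98e-05), ins-2 from 412 ± 50.6 to 83.2 ± 101 CPM (log2 −2.12) and hmg-6 from 115 ± 10.9 to 31 ± 15.8 CPM (log2 −1.80). Body wall muscle genes rose in 16 of 34 and fell in 0 (19 and 0 adjusted over the list alone; camera adjusted p = 1.08e-09; adjusted p = 0.15 with an estimated correlation), with the paramyosin gene unc-15 at 62.2 ± 71.9 and 384 ± 82.1 CPM and the troponin T gene mup-2 at 80.1 ± 89.6 and 458 ± 127 CPM. This count was 8 without replicate 1 (median log2 change 1.42) and 7 without the 4 libraries with most vitellogenin (1.21), a set chosen after the data were seen, and 15 without replicate 3. Cilia genes rose in 9 of 36 (15 adjusted over the list alone; camera adjusted p = 5.81e-07; adjusted p = 0.148 with an estimated correlation), a count of 2 without replicate 1 (median log2 change 1.32) and of 1 without those 4 libraries (0.88). Cell division genes fell in 9 of 41 (13 adjusted over the list alone; camera adjusted p = 1.96e-11; adjusted p = 0.152 with an estimated correlation), with mcm-7 at 515 ± 88.6 and 222 ± 60.8 CPM, a count of 1 without replicate 1 and of 0 without those 4 libraries (8 at an unadjusted p under 0.05). Under scaling to the spike-ins 10 body wall muscle and 2 cilia genes rose, and 0 cell division genes fell (edgeR, 0 at an unadjusted p under 0.05), with median log2 changes of 1.78, 1.83 and −0.20. In all, 511 genes were higher and 123 lower (edgeR), and under scaling to the spike-ins 131 were higher and 0 lower. Higher and lower genes numbered 314 and 62 without 270 min replicate 1 and 339 and 44 without 330 min replicate 2. Without 330 min replicate 1, 45 were lower, and without 270 min replicate 2, 41 were lower and the higher count also moved by more than 1.5-fold. Without replicate 2 in both stages, 9 were higher and 3 lower. Without replicate 1 in both stages, 224 genes passed, 218 of them among the 634. Without the 4 libraries with most vitellogenin 109 passed, 108 of them among the 634. In these stages that set takes out only the replicate 2 libraries. It is thus no separate evidence from the fit without replicate 2, from which it differs in the libraries kept at other stages. The genes hum-6, F41C3.11, hmg-6 and mcm-7 overlap another gene, and their values are uncertain.

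Cilia, body wall muscle, pan-neuronal and intestinal lists had more genes higher than lower from 330 to 410 min, and cell division genes more lower than higher. The insulin-like gene ins-6 went from 0 counts to 121 ± 49.0 CPM (at least 85.9-fold higher, adjusted p = 2.96e-09), dyf-4, needed for dye filling of sensory cilia, from 0 counts to 97 ± 29.6 CPM (at least 71.4-fold) and mboa-1 from 0 counts to 103 ± 26.4 CPM (at least 69.9-fold). The gene ces-2 fell from 463 ± 6.76 to 11.8 ± 2.54 CPM (log2 −5.23, SE 0.333), the cuticlin-like gene cutl-2 from 429 ± 21.6 to 14.4 ± 6.29 CPM (log2 −4.98) and the sugar transporter gene swt-3 from 50.3 ± 23.5 CPM to 0 counts (at least 17.7-fold lower). Cilia genes rose in 26 of 36 and fell in 1 (31 and 1 adjusted over the list alone; camera adjusted p = 1.2e-07; adjusted p = 0.224 with an estimated correlation), including mks-2 (2.44 ± 2.82 to 53.98 ± 33.4 CPM) and dyf-3 (3.95 ± 4.16 to 44.1 ± 21.4 CPM), and hyls-1 fell. Body wall muscle genes rose in 23 of 34 and fell in 1 (24 and 1 adjusted over the list alone; camera adjusted p = 0.00103; adjusted p = 0.438 with an estimated correlation), with the calponin-related gene unc-87 at 16.05 ± 3.06 and 195 ± 4.31 CPM and the titin gene ttn-1 at 107 ± 75.5 and 687 ± 481 CPM. The myogenic factor gene hlh-1 fell (log2 −1.31). Pan-neuronal genes rose in 10 of 24, with the same count adjusted over the list alone (camera adjusted p = 0.00451; adjusted p = 0.334 with an estimated correlation), among them the synaptic gene unc-13 (1.78 ± 3.08 to 50.0 ± 17.9 CPM). Intestinal genes rose in 9 of 17 and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.00718; adjusted p = 0.278 with an estimated correlation), with the peptide transporter gene pept-1 at 0.593 ± 1.03 and 116.2 ± 39.2 CPM. Cell division genes fell in 25 of 41 and rose in 1 (28 and 1 adjusted over the list alone; camera adjusted p = 8.61e-11; adjusted p = 0.167 with an estimated correlation), with bub-1 at 106 ± 15.9 and 19.2 ± 6.73 CPM. Scaled to the spike-ins, 11 cilia, 4 body wall muscle, 5 pan-neuronal and 4 intestinal genes rose, with median log2 changes of 1.89, 0.94, 0.18 and 0.52 against 2.38, 1.23, 0.49 and 0.92 with the reported scaling. Without replicate 3, 11 cell division genes fell. In the miRNA pathway 4 genes fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.228), dcr-1 by log2 1.50, rde-4 by log2 1.08, alg-2 by log2 0.79 and xrn-2 by log2 0.56. In this list 1 fell under spike-in scaling, and 2 rose and 4 fell without the 4 libraries with most vitellogenin. In all, 1557 genes were higher and 927 lower (edgeR), and with library size alone as the scaling 1212 were higher and 1798 lower. Leaving out 330 min replicate 3 gave 607 lower, DESeq2 gave 542 lower, and without replicate 1, 2196 genes passed, 2016 of them among the 2484. The genes unc-87, ttn-1 and hlh-1 overlap another gene, and their values are uncertain.

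In the last step, from 410 to 500 min, more pharyngeal and pan-neuronal genes rose than fell, and more cuticle and apical matrix genes fell than rose. The ligand-gated channel gene lgc-22 went from 0 counts to 336.5 ± 214 CPM (at least 127-fold higher, adjusted p = 2.03e-05), F30A10.2 from 0 counts to 291 ± 174 CPM (at least 108-fold) and ZK1025.3 from 0 counts to 249 ± 164 CPM (at least 73.1-fold). The zinc finger gene ztf-30 went from 304 ± 86.4 CPM to 3 counts (ratio 121, 95% counting interval 41.0 to 591), C04A11.2 from 79.9 ± 10.9 CPM to 3 counts (ratio 33.96, 11.2 to 168) and the glucuronosyltransferase gene ugt-57 from 198 ± 30.7 to 5.35 ± 2.74 CPM (log2 −5.10, SE 0.417). Pharyngeal genes rose in 8 of 15 and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.0175; adjusted p = 0.334 with an estimated correlation): the pharyngeal myosin genes myo-5 (0 counts to 130 ± 99.4 CPM) and myo-1 (1.92 ± 3.33 to 103 ± 50.0 CPM) and the pharyngeal gland gene phat-5, one of similar copies and so uncertain, rose. The 1 lower gene was peb-1, which fell from 958 ± 160.5 to 162 ± 23.1 CPM. Pan-neuronal genes rose in 9 of 24 (10 adjusted over the list alone; camera adjusted p = 0.0255; adjusted p = 0.46 with an estimated correlation), with the neuropeptide-processing gene egl-21 at 77.4 ± 37.5 and 324 ± 142 CPM. Cuticle and apical matrix genes fell in 14 of 27 and rose in 4 (15 and 5 adjusted over the list alone; camera adjusted p = 0.00364; adjusted p = 0.403 with an estimated correlation): sym-1 went from 1008 ± 251 to 75.2 ± 34.2 CPM and mlt-11 from 1174 ± 147 to 210.0 ± 34.6 CPM. In contrast cut-6 rose from 2.41 ± 4.18 to 327 ± 6.27 CPM. Epidermal genes fell in 11 of 29 and rose in 3 (11 and 4 adjusted over the list alone; camera adjusted p = 0.00475; adjusted p = 0.396 with an estimated correlation), with the spectrin gene sma-1 at 866 ± 81.6 and 232 ± 50.98 CPM. This count was 7 lower and 5 higher without replicate 1, and 5 lower and 3 higher without replicate 3. Cell division genes fell in 18 of 41 (19 adjusted over the list alone; camera adjusted p = 9.14e-07; adjusted p = 0.334 with an estimated correlation). With spike-in scaling 4 pan-neuronal genes rose, 6 cuticle genes fell and 3 rose, 2 epidermal genes fell and 1 rose, and 7 cell division genes fell. Median log2 changes of these 4 lists were then 0.64, −1.02, −0.49 and −1.019, against 0.71, −0.91, −0.39 and −1.035 with the reported scaling. In all, 1203 genes were higher and 611 lower (edgeR), and with library size alone as the scaling 995 were higher and 791 lower. Without replicate 1, 1771 genes passed, 1532 of them among the 1814. The gene sym-1 overlaps another gene, and its value is uncertain.

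**Figure D5:**
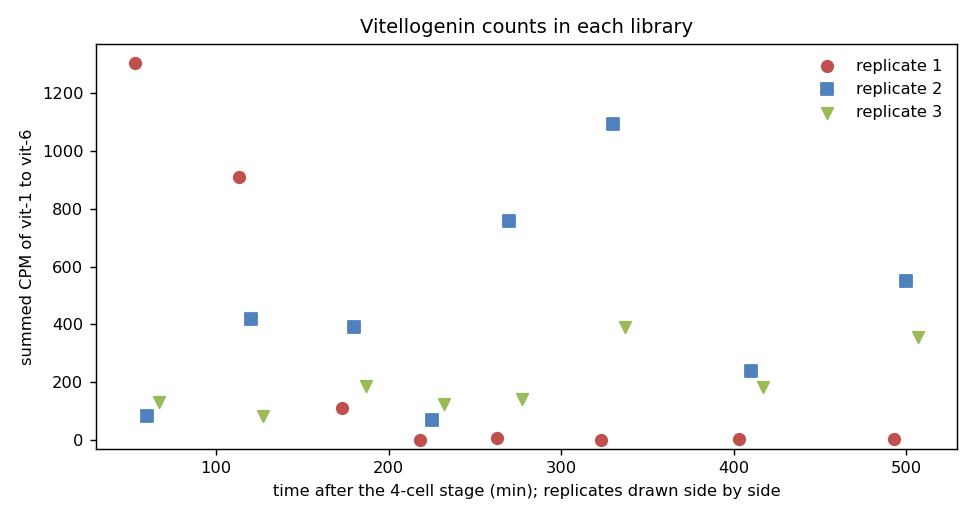
Summed CPM of the vitellogenin genes vit-1 to vit-6 (y axis) in each of the 24 libraries against minutes after the 4-cell stage (x axis), coloured and shaped by replicate, with replicates drawn side by side. Values ranged from 0 CPM at 225 min replicate 1 and 330 min replicate 1 to 1305 CPM at 60 min replicate 1.

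The cell death, stress and adult lists did not pass their list tests between 60 and 500 min. Programmed cell death genes split, 8 of 19 higher and 8 lower, also when adjusted over the list alone, with a median log2 change of 0.05, a mean of −0.05 and a downward list test (camera adjusted p = 0.168). Under scaling to the spike-ins 5 were higher and 8 lower. The gene ces-2 had 0 counts at 60 min, 718 CPM at 270 min and 10.7 CPM at 500 min, ces-1 had 0 counts, 67.5 CPM and 9.43 CPM, and the nuclease gene crn-1 fell from 338 ± 26.6 to 6.88 ± 5.01 CPM. Of 5 stress genes the mitochondrial chaperone genes hsp-60 (76.6 ± 11.4 to 418 ± 109 CPM) and hsp-6 (log2 0.68) rose and the endoplasmic reticulum chaperone gene hsp-4 fell (log2 −1.94), also when adjusted over the list alone (camera adjusted p = 0.943). Of 8 tested genes of adult soma and sperm, 1 passed, spp-1 (8.12 ± 4.64 to 53.5 ± 24.2 CPM), also when adjusted over the list alone. That list had a median log2 change of 0.25, a mean of 0.39 and a downward list test (camera adjusted p = 0.812), and 4 of its genes were higher without replicate 1. The genes ces-1 and spp-1 overlap another gene, and their values are uncertain.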

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

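The tests of developmental timing, adult collagens and clipping were chosen only after the result was seen.

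The ERCC spike-ins, which the comparisons do not use, were singled out because they carried a signal above what a count of 0 allows. Worm counts per spike-in count ranged from 8.8 at 120 min replicate 1 to 41.4 at 330 min replicate 3. The spike-in sum was saturated, with 4 spike-ins at 1023 in all 24 libraries and 9 in at least 1. It ranged over 1.84-fold between libraries and the worm total over 5.67-fold, so the ratio followed worm depth and gives no measure of RNA content.

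The replicate 1 libraries shared a deviation from the other series, with sfa-1 (140.2 against 42.87 CPM, log2 1.71) and Y54E10A.10 (580.1 against 277.5 CPM, log2 1.04) higher and rhi-1 (48.4 against 123.9 CPM, log2 −1.48) lower in replicate 1. A term for the series called 1568 genes (edgeR), and 1655 after the collision correction, against 0 for series 2 (865 at an unadjusted p under 0.05) and 0 for series 3 (423). When series 2 or 3 was tested, the replicate 1 deviation stayed in the spread, so these 0 calls cannot show that only series 1 deviated. Deviations from the stage mean also correlated between libraries of series 2 (median 0.131). Lower depth was argued against, since 957 genes called in the 6 other stages kept a median signed difference of 0.492 at 330 and 410 min (86.4% in the same direction), where replicate 1 was deeper than another replicate, and so were reads shared between overlapping genes, whose share among called genes was 0.983 times that of other genes (30.01 against 30.54%, Fisher's exact p = 0.691). A shift in developmental timing in 1 direction was argued against by a Pearson r of −0.049 across the called genes with the change from 60 to 500 min. For single steps r was −0.303 to 0.244 (genes are not independent replicates). A shift forward early and backward late could cancel in the first r and stays open. Replicates 1, 2 and 3 lay at 190, 190 and 185 min for 180 min. Replicate 1 lay earliest for 410 and 500 min, at 400 and 490 min. Handling and library preparation stay open and untested, and series 1 labels follow another naming scheme than series 2 and 3. No biological explanation apart from timing was tested, since the design names none for the series.

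Vitellogenin counts differed between replicates of 1 stage, and a candidate explanation is RNA carried over from the adults that were cut to release the embryos. The mean of adult soma transcripts, from a list written before the test, followed the vitellogenin sum across 24 libraries within stages (Pearson r 0.814, permutation p = 2e-05; Spearman correlation 0.827, p = 1e-05, the smallest p permutations can give), and r was 0.818 without the 2 farthest libraries and 0.914, 0.871 and 0.922 within series 1, 2 and 3. Of 34 listed genes 25 had at least 24 counts and 20 of these had r over 0.3, col-160 (185 CPM) with 0.958 and far-2 (247.8 CPM) with 0.833, while far-1 (2853 CPM) had 0.037 and ttr-16 (866.1 CPM) 0.481, and 17 of the listed genes were among the 8279 tested in embryos, 12 of them higher at 500 min. The 4 adult collagens gave r 0.946 (permutation p = 6e-05; Spearman correlation 0.930, p = 2e-05; 0.946 without the 2 farthest). No single vitellogenin count exceeded 102, and no biological explanation was tested.

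No count exceeded 1 highest value shared by all libraries, and distinct identifiers running out may be the reason. For genes over 500 counts the log2 ratio of the deepest to the shallowest replicate lay below that of genes with 50 to 200 counts by a median over stages of −0.448, between −0.793 at 330 min and −0.171 at 270 min. After the collision correction this median was −0.0574, between −0.324 and 0.186. Clipping alone was argued against by that deficit below the limit and by 11 worm values at 1023 against 247 from 900 to just below it, whereas 134 spike-in values stood at 1023 against 129 just below, as either explanation allows. Identifiers of 5 bases have 1024 forms rather than 1023, and this difference stays unexplained. The labels do not say whether identifiers were counted, and no biological explanation was tested.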

How the results depend on the processing

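Alternatives added after the data were seen were the collision correction, genes over 500 counts left out, spike-in scaling and the 4 libraries with most vitellogenin left out.

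Among the main results, 265 values under alternatives chosen beforehand stayed within 1.5 times the reported count and 44 moved further, and of those under added alternatives 60 stayed and 16 moved. For named genes and lists the numbers were 1310 and 34 for the former and 308 and 24 for the latter. None of the 20 genes with the largest changes of 500 against 60 min changed direction or left its side of the threshold, with adjusted p of at most 1.59e-05 over their alternatives. For 500 against 60 min, leaving out libraries gave 3408 to 3744 genes higher and 2513 to 2872 lower, and the time course gave 6766 to 7587.

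Leaving out 1 library or 1 series gave 1190 to 1868 genes higher at 120 min, and 276 to 606 higher and 381 to 732 lower at 180 min. It gave 77 to 240 higher and 47 to 194 lower at 225 min, and 261 to 677 higher and 95 to 323 lower at 270 min. At 330 min it gave 9 to 610 higher and 3 to 170 lower, with the lowest of each without replicate 2. Ranges were 952 to 1596 higher and 370 to 953 lower at 410 min, and 746 to 1229 higher and 314 to 565 lower at 500 min. Each of these is a comparison with the stage before, and the cause was not tested. Where a stage was left with 2 libraries the spread was still pooled over all stages.

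The step from 270 to 330 min depended most on single libraries. It gave 94 higher and 15 lower without the 4 libraries with most vitellogenin, and 622 genes passed without replicate 3 in both stages. In this step leaving out those 4 libraries takes out the same libraries as leaving out replicate 2.

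Spike-in scaling gave 627 higher and 677 lower at 120 min, 191 and 214 at 180 min, 61 and 45 at 225 min, and 311 and 35 at 270 min. At 330 min it gave 131 and 0 by edgeR, with 25 lower at an unadjusted p under 0.05, at 410 min 568 and 363, and at 500 min against 410 min 544 and 175. Only the 69 spike-ins with no value over 500 set this scaling. They held 13.8% of the spike-in counts, and their sum ranged over 5.89-fold between libraries.

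Library size alone gave 1798 genes lower at 410 min, and 488 and 594 genes with their highest mean at 270 and 330 min. DESeq2 gave 542 lower at 410 min, and its size factors gave 240 genes with their highest mean at 225 min. With library size alone the majority of calls turned from higher to lower at 410 min (1212 and 1798) and from lower to higher at 180 min (813 and 637). At 120 min it turned to lower with DESeq2 size factors (1755 and 1877), by DESeq2 (1606 and 1718), with spike-in scaling and without replicate 1 (1721 and 1727). In 10 of 256 pairs of list and comparison the majority turned under another scaling, the collision correction, without replicate 1 or without the 4 libraries with most vitellogenin, among them respiratory genes at 500 against 60 min (8 and 2 to 5 and 12 with library size alone), ceh genes at 410 min (6 and 4 to 3 and 8 with library size alone) and epidermal genes at 410 min (11 and 4 to 2 and 3 with spike-in scaling). With an estimated correlation 5 of the 80 list tests passed. For all of these changes the cause was not tested.

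The labels state no pairing by replicate number, and the reported fit used none. Replicates 1 and 2 of a stage share a running sample number, so the labels leave open whether they are separate samples. Their counts differed by a chi-square per degree of freedom of 2.762 (225 min) to 5.539 (500 min), where sampling noise alone gives about 1. Their vitellogenin sums were 1305 and 84.4 CPM at 60 min and 0 and 1095 CPM at 330 min. This argues against 1 shared RNA sample there. Deviations from the stage mean correlated from −0.196 to 0.434 between libraries of 1 number, above 0.1 in 48 of 84 pairs, and 17 of 24 libraries correlated best with their own number. Within series 1 every pair correlated positively (lowest 0.055, median 0.21), while the lowest and median were −0.03 and 0.131 in series 2 and −0.196 and 0.06 in series 3. With the replicate block, 6756 genes passed for 500 against 60 min and 189 were lower for 330 against 270 min, and 98.9 to 99.9% of the calls of each contrast were made again. DESeq2 made 80 to 97.2% of the calls again, and the collision correction 96.1 to 99.2%.

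A single count stood for up to 5.79 CPM, and simulated changes of 1.5-fold were recovered in 6.9% of genes. The simulation changed far fewer genes than were called in the data.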

Other observations

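The X chromosome counts, the library positions and the maternal transcripts of 1 library were chosen only after the result was seen.

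Gene families written as symbol patterns were also compared between 60 and 500 min. Some did not pass their list test, and none passed with an estimated correlation unless stated. Counts adjusted over the list alone were the same except where given. Ribosomal protein genes rose in 75 of 78 and fell in 1 (camera adjusted p = 1.69e-13; adjusted p = 0.465 with an estimated correlation), with rpl-11.2 from 94.09 ± 20.64 to 1860 ± 516.6 CPM (SD, n = 3) and rpl-25.1 at log2 4.01, while rpl-11.1 fell (log2 −0.73). In this family 76 genes exceeded 500 counts in a library. Proteasome genes fell in 29 of 32 and rose in 0 (camera adjusted p = 1.08e-06; adjusted p = 0.29 with an estimated correlation), among them rpn-13 from 211.9 ± 30.85 to 30.64 ± 17.39 CPM and rpn-12 from 389.2 ± 70.27 to 67.59 ± 10.64 CPM. Histone genes fell in 20 of 28 and rose in 5 (camera adjusted p = 0.0343; adjusted p = 0.434 with an estimated correlation). The linker histone gene hil-7 rose from 12 ± 10.29 to 2265 ± 905.2 CPM and his-60 went from 79.54 ± 20.58 CPM to 0 counts, at least 35-fold lower. Histone gene copies are near-identical and their separate values are uncertain.

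Nuclear receptor genes rose in 69 of 78 and fell in 2 (70 and 2 adjusted over the list alone; camera adjusted p = 0.000477; adjusted p = 0.34 with an estimated correlation), with nhr-3 from 1.037 ± 1.796 to 214.7 ± 18.41 CPM and nhr-2 from 279.5 ± 72.21 CPM to 0 counts. The median log2 change of this family was 3.82, or 3.37 with genes of 0 counts at their bound. Hedgehog-related genes rose in 16 of 16 (camera adjusted p = 1.59e-06; adjusted p = 0.0977 with an estimated correlation), with a median of 7.42 or 6.92 at the bounds, and grl-5 went from 0 counts to 257.4 ± 158.1 CPM, at least 158-fold higher. From 410 to 500 min 14 rose and 1 fell, and this test passed both ways (camera adjusted p = 3.03e-15; adjusted p = 0.0277 with an estimated correlation). In that step grl-7 rose from 5.931 ± 5.769 to 701 ± 305 CPM and wrt-10 fell from 1303 ± 274.3 to 66.86 ± 24.35 CPM.

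Vacuolar ATPase genes rose in 18 of 18 from 60 to 500 min (camera adjusted p = 0.00106; adjusted p = 0.076 with an estimated correlation), with vha-6 from 2.673 ± 4.63 to 117.5 ± 24.97 CPM and vha-11 from 62.52 ± 16.56 to 499.1 ± 111.6 CPM. From 330 to 410 min 14 rose (16 adjusted over the list alone; camera adjusted p = 1.59e-06; adjusted p = 0.0277 with an estimated correlation) and from 410 to 500 min 15 rose (16 adjusted over the list alone; camera adjusted p = 1.72e-05; adjusted p = 0.044 with an estimated correlation). Under spike-in scaling 1 rose in each of these steps, with median log2 changes of 0.53 and 0.54 against 0.91 and 0.67 with the reported scaling. From 410 to 500 min 2 rose without replicate 2 and 6 without replicate 3. Of 10 flp neuropeptide genes 9 rose from 60 to 500 min (camera adjusted p = 0.0228; adjusted p = 0.334 with an estimated correlation) and 9 from 410 to 500 min (camera adjusted p = 1.14e-06; adjusted p = 0.0339 with an estimated correlation), among them flp-11, which overlaps another gene and is uncertain, from 0 counts to 48.46 ± 11.31 CPM. Of 22 nlp neuropeptide genes 18 rose and 2 fell from 60 to 500 min (camera adjusted p = 0.0667), with nlp-53 from 0 counts to 114.7 ± 15.97 CPM and nlp-11 from 22.91 ± 3.567 to 1.283 ± 1.179 CPM.

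Innexin and claudin-like genes rose in 20 of 24 and fell in 4 (camera adjusted p = 0.00276; adjusted p = 0.309 with an estimated correlation), and inx-22 fell from 67.02 ± 12.03 to 1.793 ± 1.597 CPM. T-box genes fell in 6 of 9 and rose in 1 (camera adjusted p = 0.00715; adjusted p = 0.152 with an estimated correlation), with tbx-33 from 292 ± 28.9 CPM to 0 counts and tbx-2 from 43.46 ± 29.74 to 149.7 ± 34.9 CPM. Of 35 ceh homeobox genes 20 rose and 12 fell (camera adjusted p = 0.834), ceh-48 from 0.6683 ± 1.158 to 140.6 ± 20.62 CPM and ceh-83 from 121.2 ± 10.25 CPM to 0 counts. Of 35 col collagen genes 19 rose and 0 fell (camera adjusted p = 0.0907), and of 11 puf and cey genes 2 rose and 8 fell (camera adjusted p = 0.139), with puf-7 from 86.22 ± 8.709 to 2.055 ± 2.362 CPM. Respiratory complex genes had 8 higher and 2 lower of 28 (8 and 0 adjusted over the list alone; camera adjusted p = 0.857), but 5 higher and 12 lower with library size alone, and their median log2 change of 0.11 stood against a downward list test. Of 30 major sperm protein genes 0 had counts enough for a test.

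Ribosomal protein genes rose in 63 of 78 and proteasome genes fell in 23 of 32 already from 60 to 120 min (69 and 25 adjusted over the list alone; camera adjusted p = 8.33e-10 and 3.85e-08; adjusted p = 0.545 and 0.216 with an estimated correlation). Spike-in scaling gave 3 and 10 in their place, with median log2 changes of 0.81 and −1.01 against 0.92 and −0.94 with the reported scaling. From 330 to 410 min 37 ribosomal protein genes rose and 0 fell (71 and 1 adjusted over the list alone). The rising genes numbered 56 with DESeq2 size factors and 69 without the 4 libraries with most vitellogenin. With library size alone 0 rose and 2 fell, with spike-in scaling 0 passed (edgeR, 0 at an unadjusted p under 0.05), and without replicate 1 or with the collision correction 2 rose and 1 fell. Median log2 changes were 0.559 without replicate 1, 0.352 with the collision correction, 0.295 with library size alone and 0.312 with spike-in scaling. With DESeq2 size factors the median was 0.695. Without replicate 3, 0 passed (edgeR, 0 higher and 1 lower at an unadjusted p under 0.05).

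Genes on the X chromosome made up 730 of 3772 genes higher at 500 min (19.4%) and 193 of 2741 lower (7.04%), an odds ratio of 3.17 (Fisher's exact p = 4.39e-48), against 1119 of 8212 tested genes (13.6%). Of the genes with their highest mean at 60 min, 68 of 1794 (3.8%) were on X, and at 120 min 161 of 943 (17.1%). The share of all counts on X was 7.04 ± 0.3% at 60 min, 11.04 ± 0.15% at 120 min and 14.66 ± 0.79% at 500 min (SD, n = 3).

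At 410 min, replicate 2 held maternal transcripts that the other 2 libraries of that stage held at lower levels. In replicates 1, 2 and 3, oma-1 stood at 3.14, 110.9 and 0 CPM, mex-5 at 3.14, 113.3 and 0 CPM, nos-2 at 3.14, 89.2 and 0 CPM and mex-1 at 0, 79.55 and 5.76 CPM. In replicate 2 these were 46, 47, 37 and 33 counts, and pes-10 and tbx-38 had 0 counts there.

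Placed along the mean course of the other 2 series by their Pearson correlation across genes, most libraries lay within 10 min of their label. The exceptions were 225 min replicate 2 at 210 min, 270 min replicate 3 at 295 min, 330 min replicate 3 at 310 min and 330 min replicate 2 at 345 min.

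Relabelling the 24 libraries at random gave as many genes over time in 1 of 100 splits, the real one with 7585 genes. The highest other had 2176. A share of 1 in 100 is the smallest that these splits allow. Relabelled groups mix stages, which widens the spread within a group and lowers the calls, so the comparison cannot exclude chance. The 6 libraries of 2 stages make 10 splits, too few for a share under 0.05, and every split but the real one mixes the 2 stages. The real split and the highest other called 6565 and 0 genes for 500 against 60 min, 3612 and 2 for 120 min, 1439 and 0 for 180 min, 467 and 0 for 225 min, and 1019 and 0 for 270 min. For 330 min they called 634 and 0, for 410 min 2484 and 1, and for 500 against 410 min 1814 and 0.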
